A study of Danio rerio with 8 samples.

How the data were processed

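Liver RNA of zebrafish (Danio rerio) labelled 18, 26 or 34 °C was measured on 8 Agilent 2-colour microarrays. On such an array a Cy5-labelled (red) and a Cy3-labelled (green) RNA sample bind the same probes, and the ratio of their signals is read. Per the labels, total RNA was extracted with Trizol and labelled by version 5.7 of Agilent's 2-colour protocol. The 8 arrays joined 7 RNA samples in a loop, in which neighbouring arrays share a sample. The samples were 2 each at 18, 26 and 34 °C on day 28, and 1 at 26 °C on day 4. The labels call the replicates biological and do not say how many fish each one holds.

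The deposited table holds 1 log2 ratio per probe and array, normalized by the authors. The submitters' processing notes name limma, with no version. The background correction, the normalization method and the spot filters are not given in the sources used here. The log base is not stated either. It was taken as log2, the base limma uses, because the values span -8.96 to 8.03 and a log10 ratio of 16-bit signals cannot exceed 4.82 in size. The dyes of each sample come from the labels. Whether each deposited ratio is Cy5 over Cy3 or the reverse is not given in the sources used here. It was read as Cy5 over Cy3, which is likely because limma defines ratios that way and the array titles name the Cy5 sample first. If the reverse holds, every signed value below turns. Sizes, counts, p-values and the opposition between gene groups stay as they are.

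Array medians lay between -0.000725 and 0.00385, and array SDs between 0.315 and 0.537. Between 43.2% and 82.8% of the probes of an array lay within 0.1 of 0. The table gives ratios without channel intensities, so probes near background could not be told from unchanged ones, and small ratios may be compressed. The number of arrays limits the precision. No value was missing among 43603 probes.

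Probes were named through the platform annotation, with symbols updated by Entrez ID (23534 probes) or transcript accession (42 probes) from a RefSeq gene table of the GRCz12tu assembly; 141 kept the platform's symbol. In all, 23717 probes (54.4%) had 1 symbol, 0 had several and 19886 had none here. No genome build is named for the array, so no coordinates are given. Probes of 1 symbol were averaged and unnamed probes were kept on their own, which left 35434 features, 15548 of them with a gene symbol. Among 6107 genes with several probes, 2475 had probes of opposite sign at 34 °C against 18 °C.

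The analysis had 2 steps, since arrays that share an RNA sample are not independent. First, the 8 log2 ratios of each feature were fitted by least squares on the 7 RNA samples and a dye term, which left 1 residual degree of freedom. This gave each sample a level relative to the mean of all 7 samples. Second, limma (version 3.58.1, R 4.3.3; lmFit and eBayes) compared the 4 groups on these levels, with 3 residual and 1.63 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. The comparisons were 34 °C against 26 °C, 18 °C against 26 °C and 34 °C against 18 °C on day 28. Day 4 against day 28 at 26 °C was secondary, and its lone day 4 sample was assumed to vary like the others. Errors given as ± are limma's moderated standard errors. P-values rest on the spread within the 3 replicate pairs of day 28, to which the lone day 4 sample adds nothing. The sample levels come from shared arrays, so their errors are correlated, which the second step ignores.

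The comparisons, alternatives and 41 gene lists (28 pathways and 13 sets of cell type or tissue markers) were fixed before the data were examined. Each list was tested with camera in limma, at a preset inter-gene correlation of 0.01, and adjusted over 123 tests. Camera was repeated with the correlation estimated for each list. In that form camera also tests on at most the 3 residual degrees of freedom, which raises p-values whatever the correlation. Desaturation and elongation genes at 18 °C against 26 °C, with an estimated correlation of -0.049, went from a camera p of 3.5e-05 to 0.022. Named genes followed a rule. Where at least 5 genes passed in a direction, it took up to 10 with the largest change whose groups did not overlap, leaving out clone and locus names. Otherwise it took the 5 with the smallest p, given as values that did not pass. It added up to 4 members of each described list and 8 temperature genes, of which vtg1 was not measured here.

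The steps were tested on simulated arrays with the real features and spreads, 5 runs for each of 2 ratios of between-sample to between-array variance (0 and 0.5). At 34 °C against 18 °C, changes of 4 on the log2 scale were recovered in 99.2% and 97.4% of cases, and changes of 2 in 94.6% and 92%. At 34 °C against 26 °C, changes of 1 were recovered in 82.2% and 72.4%. These changes were planted in features drawn at random from all, whose median standard error in the real fit was 0.062. The recovery percentages do not apply to genes with larger standard errors. Between 1.55% and 3.43% of unchanged features had an unadjusted p below 0.05 in the sample-level fit, and between 4.74% and 12.4% did in limma fitted directly on the arrays. A list of 40 genes shifted by 0.3 was called in 5 of 5 runs at both ratios with the preset correlation, and in 5 and 2 runs with an estimated one. Unshifted lists were called 0 times in 200 at each ratio. The simulated genes varied independently of each other. These runs therefore could not show how often the preset correlation calls unshifted lists of correlated genes. Nor could they show what share of unchanged features has a small p where samples differ in many genes at once.

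Alternatives were median-centred and scale-normalized arrays, no dye term, limma or generalized least squares on the arrays, single probes, fits of the compared groups alone, a replicate block, each sample or array left out, robust eBayes and stricter thresholds. Scale normalization gave every array the same median absolute ratio. A variance ratio from the 25% most variable features and marker covariates were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.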

Results

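Transcript ratios were measured in zebrafish liver at 3 temperatures, in a series made to choose probes for a custom microarray by their response to temperature. Liver RNA at 18, 26 and 34 °C on day 28 came as 2 samples each, and 1 further sample came from 26 °C on day 4. The 8 arrays placed each RNA sample on 2 of them, once with each dye, except that replicate 1 at 34 °C and replicate 2 at 26 °C lay on 3. Across features, which are not independent replicates, the levels of the replicates correlated at 0.40 for 18 °C, 0.46 for 34 °C and -0.03 for 26 °C on day 28. The 26 °C replicates still differed least in size. The SD of replicate 1 minus replicate 2 was 0.226 there, against 0.273 at 18 °C and 0.278 at 34 °C. The levels of the 7 samples sum to 0 by construction, so unrelated samples correlate slightly below 0. Across the 8 arrays, 28 of 28 pairs correlated with the sign that their temperature differences give. The deposited orientation of the arrays had the smallest residual of 128 patterns in the fit with a dye term, and rank 4 without it.

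The ratios were read as Cy5 over Cy3. A positive change therefore means a higher level at the first-named temperature, and it means a lower level there if the deposited ratios are Cy3 over Cy5, which the sources used here do not exclude. This holds for every signed value in the text.

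The comparison of 34 °C with 18 °C on day 28 spans the whole temperature range of the series. Among the named genes past the threshold, elovl2, an elongase of long polyunsaturated fatty acids, had the largest positive change. It was 3.91 ± 0.38 on the log2 scale (SE, n = 2 against 2). Next came the fatty acid-binding protein fabp7a (3.55 ± 0.33) and the desaturase fads2 (3.40 ± 0.28). Further positive changes were those of rab1aa, a small GTPase of vesicle transport (3.36 ± 0.26), and abcd3a, a peroxisomal fatty acid transporter (3.05 ± 0.28). The largest negative ones were nanog, a pluripotency factor that fish eggs also store as RNA (-2.91 ± 0.33), and zp3a.1, a glycoprotein of the egg envelope (-2.68 ± 0.28). In all, 348 of 35434 features changed (limma, adjusted p below 0.05), 172 positive and 176 negative, and 203 of them by at least 2-fold. Of 123 list tests over the 3 comparisons on day 28, 69 were called with the preset correlation, 41 positive and 28 negative, 25 of them in this comparison, and 0 with an estimated correlation (lowest adjusted p = 0.301).

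The other named genes with positive changes were the peroxiredoxin prdx2 (2.88 ± 0.28), the thioredoxin txnb (2.66 ± 0.16), the mitochondrial folate carrier slc25a32a (2.76 ± 0.18), apoa4b.1 (2.75 ± 0.30) and pnp4b (2.61 ± 0.23). Their limma adjusted p-values ran from 0.0299 for txnb to 0.0478 for apoa4b.1. On the negative side stood parn, a deadenylase that shortens poly(A) tails (-2.61 ± 0.18), the ubiquitin hydrolase uchl1 (negative, 5.65-fold), jpt1b (-2.32 ± 0.14), the oocyte storage particle protein 42sp43 (-2.31 ± 0.26) and fbxo43, an inhibitor of meiotic exit in eggs (-2.28 ± 0.22). Also negative were lpcat4 (-2.31 ± 0.25), retsatl (-2.26 ± 0.17) and ppt2a.1 (-2.09 ± 0.23). Limma adjusted p-values of these negative changes ran from 0.0272 for uchl1 to 0.0490 for nanog.

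**Figure D1:**
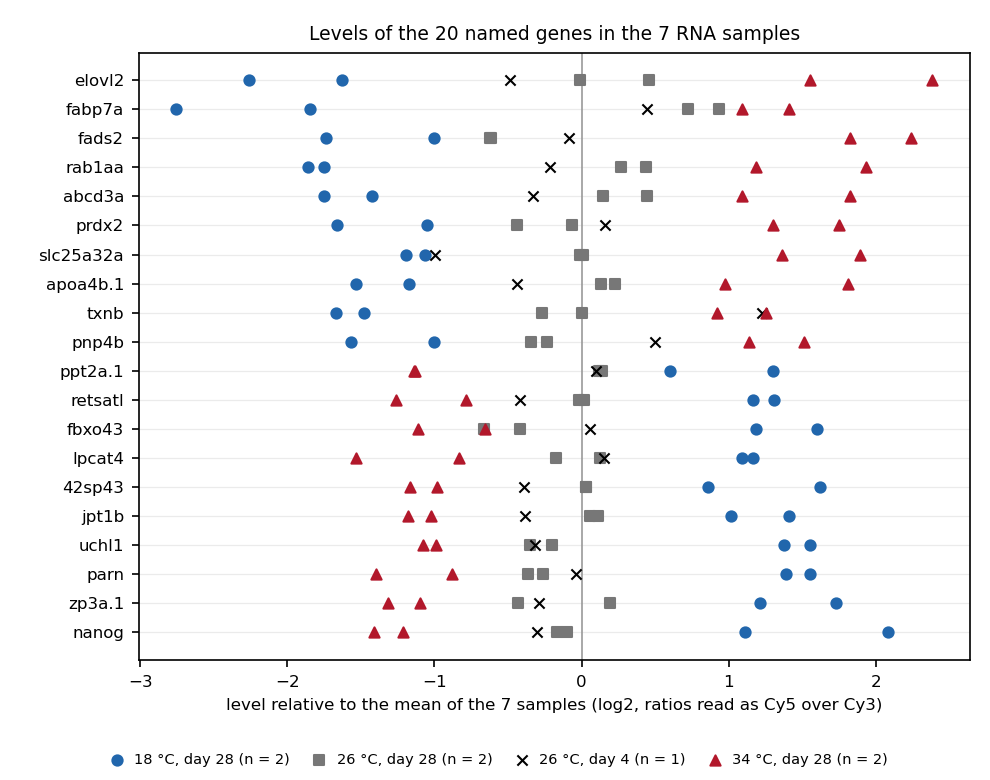
Levels of the 20 named genes at 34 °C against 18 °C (vertical axis) in each of the 7 RNA samples, on a log2 scale relative to the mean of the 7 samples and read as Cy5 over Cy3 (horizontal axis). Each point is 1 RNA sample, and in every gene both 34 °C samples lie apart from both 18 °C samples, as the naming rule required; elovl2 changed by 3.91 and nanog by -2.91.

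Of 13 measured desaturation and elongation genes, 3 changed over all features, elovl2, fads2 and elovl6 (2.41 ± 0.12), all positive, while 4 positive and 2 negative ones passed when adjusted over the list alone. The desaturation and elongation median was 0.23 (adjusted p = 0.0278, and adjusted p = 0.367 with an estimated correlation). The list for cholesterol synthesis and uptake had 13 of 18 genes positive, with 1 called over all features, a reductase of the final steps, dhcr7 (1.84 ± 0.18), and 11 adjusted over the list alone. The cholesterol median was 0.69 (adjusted p = 1.83e-06, and adjusted p = 0.367 with an estimated correlation). Fatty acid oxidation had 23 of 26 genes positive, 2 called over all features, the peroxisomal enzymes ehhadh (1.55 ± 0.13) and acaa1 (1.81 ± 0.20), and 9 adjusted over the list alone. The fatty acid oxidation median was 0.66 (adjusted p = 1.44e-09, and adjusted p = 0.367 with an estimated correlation). For apolipoproteins and lipid transport, 23 of 25 genes were positive, fabp7a and apoa4b.1 passed over all features, and 9 passed adjusted over the list alone. The apolipoprotein median was 0.81 (adjusted p = 8.03e-09, and adjusted p = 0.367 with an estimated correlation). Hepatocyte markers moved the same way and oocyte markers the opposite way in the same samples, with medians of 1.21 and -2.41.

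Genes for proteins that the liver secretes had mostly positive values, together with the hepatocyte markers. Of 39 complement and coagulation genes 35 were positive, 2 were called over all features and 25 adjusted over the list alone. The complement and coagulation median was 1.16 (adjusted p = 4.26e-15, and adjusted p = 0.367 with an estimated correlation). The called genes were serpinf2b, the plasmin inhibitor (1.64 ± 0.12), and coagulation factor f10 (positive, 3.02-fold). The transferrin gene tfa (2.28 ± 0.25) was the 1 called member of both the acute phase and iron list (17 of 21 positive, 6 passed adjusted over the list alone; median 0.62, adjusted p = 2.01e-05, and adjusted p = 0.367 with an estimated correlation) and the hepatocyte markers (20 of 21 positive, 8 adjusted over the list alone; median 1.21, adjusted p = 2.90e-11, and adjusted p = 0.367 with an estimated correlation). Of the 21 measured hepatocyte markers, 12 also belong to another of the lists. Vitellogenins, the egg yolk precursors made by liver under oestrogen, were on the same side: 10 of 11 genes of their list were positive, 7 of them past the threshold adjusted over the list alone. The vitellogenin list median was 1.93 (adjusted p = 2.41e-07, and adjusted p = 0.301 with an estimated correlation). The oestrogen receptor gene esr1 passed over all features (1.24 ± 0.12), and vtg5 (4.24 ± 0.64, adjusted p = 0.0703) and vtg4 (2.68 ± 0.42, adjusted p = 0.0744) did not. Exocrine pancreas markers had 23 of 26 genes positive and 0 called, adjusted over the list alone too (median 1.49, adjusted p = 6.06e-05, and adjusted p = 0.557 with an estimated correlation), and their median difference between the 26 °C day 28 replicates was 2.17.

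Ribosomal protein genes were mostly positive, with 68 of 71 genes positive, 5 called over all features and 36 adjusted over the list alone. The ribosomal protein median was 1.05 (adjusted p = 1.86e-26, and adjusted p = 0.301 with an estimated correlation). Called members included rpl15 (1.95 ± 0.18), rpl8 (1.72 ± 0.19), rpl10 (1.33 ± 0.13) and rpl27 (1.15 ± 0.09). Translation factors went both ways. Of 34 genes 25 were positive, and over all features the initiation factor subunit eif3d (1.83 ± 0.19) and the helicase eif4a2 (-0.92 ± 0.10) passed with opposite signs, against 12 positive and 3 negative adjusted over the list alone. The translation factor median was 1.08 (adjusted p = 1.17e-04, and adjusted p = 0.367 with an estimated correlation). Antioxidant and glutathione genes had 21 of 27 positive, with prdx2, txnb and gpx1a (positive, 5.66-fold) called, and 9 positive and 2 negative adjusted over the list alone. The antioxidant median was 0.48 (adjusted p = 6.95e-06, and adjusted p = 0.397 with an estimated correlation). Amino acid and urea cycle genes had 34 of 50 positive, with 1 called, the S-adenosylhomocysteine hydrolase ahcy (1.89 ± 0.08), and 8 positive and 1 negative adjusted over the list alone. The amino acid median was 0.18 (adjusted p = 4.24e-04, and adjusted p = 0.495 with an estimated correlation). The median of the oocyte markers, -2.41, was opposite in sign to each of these medians.

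Cell cycle genes and oocyte markers had negative medians. Of 36 genes of the cell cycle and DNA replication 31 were negative, 2 changed over all features and 27 adjusted over the list alone. The cell cycle median was -1.11 (adjusted p = 4.10e-15, and adjusted p = 0.301 with an estimated correlation). The spindle checkpoint gene mad2l1 (-1.71 ± 0.10) and the ribonucleotide reductase subunit rrm1 (-1.07 ± 0.11) were the called members. Of 18 oocyte markers 17 were negative, 1 changed over all features, zp3a.1, and 16 adjusted over the list alone. The oocyte marker median was -2.41 (adjusted p = 3.06e-14, and adjusted p = 0.336 with an estimated correlation). Values that did not pass included bmp15, an oocyte growth factor (-1.12 ± 0.15, adjusted p = 0.0577), and the oocyte linker histone h1m (-2.98 ± 0.43, adjusted p = 0.0669). A marker of the testis list, piwil1, a germline gene that ovaries express too, changed by -1.38 ± 0.07 (adjusted p = 0.0272), while that list as a whole was not called (median -0.04, adjusted p = 0.133).

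Chaperone lists had medians near 0. The endoplasmic reticulum list had 19 of 30 genes negative and 1 called, the chaperone hsp90b1 (-1.40 ± 0.14), with 2 adjusted over the list alone. The endoplasmic reticulum median was -0.15 (adjusted p = 0.0398, and adjusted p = 0.513 with an estimated correlation). The list of cytosolic heat shock proteins was not called (median -0.11, adjusted p = 0.0887), and its called member hspb8 (0.74 ± 0.05) had probes of opposite sign. Cold-inducible and RNA chaperone genes had 10 of 15 positive, 0 called over all features and 4 adjusted over the list alone (median 0.03, adjusted p = 0.0230, and adjusted p = 0.379 with an estimated correlation), among them the chromatin protein hmgb1a (2.99 ± 0.35), which did not pass over all features. None of the 7 measured genes fixed as textbook responders to temperature passed. Their values were 1.00 ± 0.32 for cirbpa, 0.63 ± 0.36 for cirbpb, 0.40 ± 0.21 for scd, -0.18 ± 0.13 for hsp90aa1.1, 1.03 ± 0.36 for hspa8, -1.07 ± 0.54 for hspa5 and -0.66 ± 0.09 for serpinh1b, with limma adjusted p-values from 0.0646 to 0.746. The probes of cirbpb disagreed in sign. The value of hsp90aa1.1 turned to 0.0078 without replicate 1 at 18 °C.

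**Figure D2:**
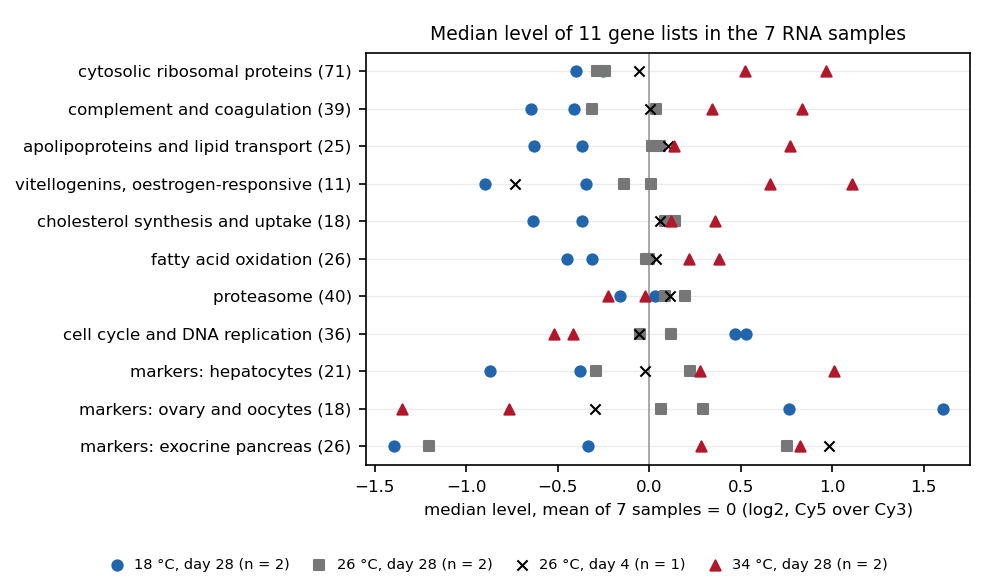
Median level of 11 gene lists (vertical axis, measured genes in brackets) in each of the 7 RNA samples, on a log2 scale relative to the mean of the 7 samples and read as Cy5 over Cy3 (horizontal axis). Each point is 1 RNA sample; at 34 °C against 18 °C the ribosomal protein list had a median change of 1.05 and the oocyte markers of -2.41, and the exocrine pancreas markers of the 26 °C day 28 samples lay at 0.75 and -1.20.

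The count of 348 was 0 without replicate 2 at 18 °C, replicate 1 at 34 °C, or either 26 °C day 28 sample, 2 without replicate 1 at 18 °C and 112 without replicate 2 at 34 °C. It was also 0 after scale normalization, with the 18 and 34 °C samples alone, or with the oocyte or exocrine pancreas marker median as a covariate, while single probes gave 226 of 43603, and limma on the arrays directly gave 2994, among them 346 of the 348.

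The comparison of 34 °C with 26 °C on day 28 covers the step from the middle to the high temperature. Ribosomal protein genes had the smallest list p-value, with 66 of 71 positive, 0 called over all features and 31 adjusted over the list alone. The ribosomal protein median was 1.05 (adjusted p = 7.84e-33, and adjusted p = 0.301 with an estimated correlation). Members were rpl27 (1.39 ± 0.09, adjusted p = 0.0818), rpl19 (1.54 ± 0.14, adjusted p = 0.159, but -0.66 without the array that joins replicate 2 of 34 °C and of 26 °C) and rpl3 (0.73 ± 0.07, adjusted p = 0.169). Proteasome genes went the other way, with 38 of 40 negative and 0 called, adjusted over the list alone too. The proteasome median was -0.30 (adjusted p = 9.34e-07, and adjusted p = 0.367 with an estimated correlation). Examples are the subunits psmd7 (-0.45 ± 0.08, adjusted p = 0.266) and psma3 (-1.33 ± 0.26, adjusted p = 0.281).

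Over all features, 0 changed at 34 °C against 26 °C by limma on the sample levels, where the lowest adjusted p was 0.0818. An unadjusted p below 0.05 was reached by 3114 features (8.79%), against 1.55% to 3.17% of simulated unchanged features. Simulated features varied independently of each other, so this difference does not show that features changed. Limma on the arrays directly called 1372, 454 positive and 918 negative, and generalized least squares called 1350, or 121 with the variance ratio of the most variable features. The smallest p-values belonged to itgb1b.2, an integrin (1.09 ± 0.04), ahcy (1.64 ± 0.08), rnf11a (1.12 ± 0.06), vdac3, a mitochondrial channel (0.92 ± 0.05), and dock8 (0.81 ± 0.05), whose probes disagreed in sign. On the negative side they were zpr1 (-0.72 ± 0.04), the replication origin protein orc3 (-0.94 ± 0.05), bin1b (-0.80 ± 0.05), mnat1 (-0.81 ± 0.05) and the RNA helicase ddx3xb (-0.61 ± 0.04). None of these 10 passed, with adjusted p-values from 0.0818 to 0.104. Without the array that joins replicate 2 of 34 °C and of 26 °C, the value of itgb1b.2 turned to -1.34.

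Complement and coagulation genes had 38 of 39 positive (median 0.66, adjusted p = 3.42e-12, and adjusted p = 0.369 with an estimated correlation), and fatty acid oxidation genes 23 of 26. The fatty acid oxidation median was 0.49 (adjusted p = 1.89e-06, and adjusted p = 0.367 with an estimated correlation). In neither list did a gene pass over all features, and 6 and 1 passed adjusted over the list alone. Cell cycle genes had 34 of 36 negative, 0 called and 3 adjusted over the list alone. The cell cycle median was -0.56 (adjusted p = 2.04e-11, and adjusted p = 0.301 with an estimated correlation). The value of mad2l1 did not pass (-0.74 ± 0.10, adjusted p = 0.228). Markers moved alongside, with medians of 0.78 for hepatocytes (adjusted p = 1.45e-07, and adjusted p = 0.397 with an estimated correlation) and -1.17 for oocytes (adjusted p = 8.60e-10, and adjusted p = 0.367 with an estimated correlation). None of these markers passed over all features, while 3 positive hepatocyte markers, 12 negative oocyte markers and 1 positive one passed adjusted over the list alone. Exocrine pancreas markers had a median of 0.87 (adjusted p = 6.74e-04, and adjusted p = 0.579 with an estimated correlation), which was -0.11 without replicate 2 at 26 °C. In all, 23 of the 41 lists were called, 17 positive and 6 negative, and 0 with an estimated correlation. The fixed temperature genes had values of 0.15 ± 0.32 for cirbpa, 0.45 ± 0.36 for cirbpb, -0.06 ± 0.21 for scd, -0.04 ± 0.13 for hsp90aa1.1, 0.16 ± 0.36 for hspa8, -0.88 ± 0.54 for hspa5 and -0.53 ± 0.09 for serpinh1b, and none passed (lowest adjusted p = 0.251). The probes of hsp90aa1.1 and hspa8 disagreed in sign. The values of cirbpa, cirbpb, hsp90aa1.1, hspa5 and hspa8 turned in sign in some fits without 1 sample or array.

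The comparison of 18 °C with 26 °C on day 28 covers the step from the middle to the low temperature. Cholesterol synthesis genes had the smallest list p-value, with 17 of 18 negative, 0 called over all features and 6 adjusted over the list alone. The cholesterol median was -0.57 (adjusted p = 1.24e-13, and adjusted p = 0.301 with an estimated correlation). Members were the lanosterol synthase lss (-0.70 ± 0.11, adjusted p = 0.427), dhcr7 (-1.04 ± 0.18, adjusted p = 0.489), ebp (-1.36 ± 0.24, adjusted p = 0.507) and hmgcs1 (-0.97 ± 0.18, adjusted p = 0.555). Oocyte markers were positive in 18 of 18 cases and hepatocyte markers negative in 20 of 21, with 0 called over all features, and 2 oocyte and 0 hepatocyte markers adjusted over the list alone. Their medians were 0.94 (adjusted p = 2.76e-12, and adjusted p = 0.367 with an estimated correlation) and -0.43 (adjusted p = 3.32e-07, and adjusted p = 0.397 with an estimated correlation).

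A single feature changed at 18 °C against 26 °C, the integrin gene itgb1b.2 (-1.39 ± 0.04, limma adjusted p = 0.0453). An unadjusted p below 0.05 was reached by 1570 of the 35434 (4.43%), against 1.93% to 3.24% of simulated unchanged features. As simulated features varied independently of each other, the difference does not show that further features changed. Limma on the arrays directly called 29, and itgb1b.2 was not among them. The values next in line did not pass. They were the fatty acid elongase elovl6 (-2.37 ± 0.12), ugt5b4 (-0.80 ± 0.05), abhd2a (-0.91 ± 0.06) and sgk2b (-0.94 ± 0.08) on the negative side, with adjusted p-values from 0.168 to 0.360. On the positive side they were uchl1 (1.74 ± 0.09), sugt1 (0.60 ± 0.05), the SUMO ligase pias4b (0.63 ± 0.05), slc12a7b (0.47 ± 0.04) and gtse1 (0.56 ± 0.05, probes of opposite sign), with adjusted p-values from 0.168 to 0.390. The call of itgb1b.2 was lost without any 1 of the 6 day 28 samples, which each time left 2 residual degrees of freedom instead of 3. Its value was 0.35 without the array that joins replicate 1 of 34 °C and of 18 °C.

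Proteasome genes were negative in 36 of 40 cases with 0 called, adjusted over the list alone too (median -0.22, adjusted p = 1.59e-09, and adjusted p = 0.367 with an estimated correlation); psmc1b stood at -0.72 ± 0.15 and psme1 at -0.92 ± 0.20 (adjusted p = 0.594 and 0.622). Ribosomal protein genes had a median of -0.06 and were not called (adjusted p = 0.344). Apolipoproteins and lipid transport had 21 of 25 genes negative, 0 called and 3 adjusted over the list alone (median -0.41, adjusted p = 4.83e-07, and adjusted p = 0.367 with an estimated correlation), such as fabp7a (-3.13 ± 0.33, adjusted p = 0.390). Desaturation and elongation genes had 9 of 13 negative, 0 called and 2 adjusted over the list alone. The desaturation and elongation median was -0.23 (adjusted p = 1.22e-04, and adjusted p = 0.301 with an estimated correlation). Cell cycle genes had 30 of 36 positive, 0 called and 1 adjusted over the list alone (median 0.49, adjusted p = 7.93e-11, and adjusted p = 0.301 with an estimated correlation), with mad2l1 at 0.96 ± 0.10 (adjusted p = 0.390). Exocrine pancreas markers had a median of -0.52 (adjusted p = 0.0408, and adjusted p = 0.721 with an estimated correlation), which was 0.40 without replicate 1 at 26 °C. In all, 21 of the 41 lists were called, 2 positive and 19 negative, and 0 with an estimated correlation. The fixed temperature genes stood at -0.85 ± 0.32 for cirbpa, -0.18 ± 0.36 for cirbpb, -0.46 ± 0.21 for scd, 0.14 ± 0.13 for hsp90aa1.1, -0.87 ± 0.36 for hspa8, 0.19 ± 0.54 for hspa5 and 0.13 ± 0.09 for serpinh1b, and none passed (lowest adjusted p = 1.00). The probes of cirbpb and hspa5 disagreed in sign. Without 1 sample or array, the values of cirbpb, hsp90aa1.1, hspa5 and serpinh1b turned in sign in some fits.

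Set side by side over all features, the 34 °C and 18 °C fold changes against 26 °C correlated at -0.34 and had a covariance of -0.0218. Both comparisons use the same 26 °C samples, and simulated unchanged groups gave a correlation of 0.50 and a covariance of 0.0116. With noise drawn per array the simulated values were 0.47 and 0.00672. With 1 of the 26 °C samples for each comparison, the correlation was -0.32 or -0.53, depending on which sample served which. The overlap of the 2 sets of calls was fixed at 0, as the sample levels gave 0 calls at 34 °C against 26 °C. Limma on the arrays directly called 10 features in both comparisons. Of these, 6 were negative at 34 °C and positive at 18 °C (0.337 expected from independent lists), 3 were the reverse (0.205 expected) and 1 was positive in both (0.167 expected).

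Day 4 was compared with day 28 at 26 °C, with 1 sample against 2. Vitellogenin and oestrogen-responsive genes had a median level of -0.73 in the day 4 sample against 0.01 and -0.14 in the day 28 samples, and oocyte markers lay at -0.30 against 0.06 and 0.30. Exocrine pancreas markers lay at 0.98 on day 4 and at 0.75 and -1.20 on day 28, so the day 28 samples differed more from each other than the day 4 sample did from replicate 1. No feature changed (limma, lowest adjusted p = 0.645), 2384 had an unadjusted p below 0.05, and limma on the arrays directly called 0. The day 4 side has no replicate check.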

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

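The generalized least squares fit with the variance ratio of the 25% most variable features, the fits with marker covariates, the overlap under the fits on the arrays and the split of the 26 °C samples were chosen after seeing the data; the other alternatives were planned. At 34 °C against 18 °C, the 348 features became 355 with centred arrays, 314 without the dye term, 247 with robust eBayes, 2994 with limma on the arrays directly, 2992 with generalized least squares over all features, 1971 with the ratio of the 25% most variable features, and 226 with single probes, where more features are tested. They became 0 after scale normalization, 0 with the compared groups alone, 0 with either marker covariate, 1 at an adjusted p below 0.01 and 203 at 2-fold or more. Leaving out 1 sample gave 0 to 348, and leaving out 1 array gave 0 to 246. At 34 °C against 26 °C, the count of 0 became 1372 with limma on the arrays directly, 1350 with generalized least squares and 121 with the ratio of the 25% most variable features; it stayed 0 without any 1 sample and was 0 to 2 without 1 array. At 18 °C against 26 °C, the count of 1 became 29 with limma on the arrays directly and 29 with generalized least squares. It was 0 after scale normalization, with the ratio of the 25% most variable features, with single probes, the compared groups alone, the replicate block, either covariate or an adjusted p below 0.01, 0 to 1 without 1 sample and 0 without any 1 array. Day 4 against day 28 gave 0 under every alternative run for it; the compared groups alone were not fitted there, nor could the day 4 sample be left out. The overlap of the responses, 0 by necessity on the sample levels, became 10 with limma on the arrays directly, 10 with generalized least squares and 0 with the ratio of the 25% most variable features. The covariance of the responses was -0.0205 and -0.0488 with 1 of the 26 °C samples for each comparison, against -0.0218. A replicate block gave 237 features at 34 °C against 18 °C, 125 of them among the 348. Whether the replicate numbers pair the samples could not be settled. Deviations from the group means correlated across features at -0.15 between 18 and 26 °C, -0.13 between 18 and 34 °C and 0.41 between 26 and 34 °C. Shared arrays can themselves make such deviations correlate, so these values do not decide it. The oocyte, hepatocyte and ribosomal protein medians differed in 1 direction between the replicates at every temperature. The fits of the compared groups alone, with a covariate, with the replicate block or without 1 day 28 sample have 2 residual degrees of freedom instead of 3. The block fit called 237 features with 2 residual degrees of freedom, but it also takes out differences that follow the replicate number. It therefore cannot show what the lost degree of freedom did in the other fits. The oocyte median followed temperature, so a fit with it as covariate cannot separate ovarian RNA from temperature. The fits on the arrays treat arrays that share a sample as independent or nearly so, and scale normalization multiplied the arrays with the narrowest ratios. Which of these properties changed a count was not tested, nor was the cause for the other alternatives. Of the 69 list calls, 0 held with an estimated correlation (14 had an unadjusted p below 0.05), 67 with centred arrays and 62 with the block, and the number called without 1 sample was 52 to 72. A sample left alone in its group was assumed to vary like the other groups. Camera with an estimated correlation also has fewer degrees of freedom, so correlation alone need not explain its 0 calls. The exocrine pancreas median turned at 34 °C against 26 °C (range without 1 sample -0.11 to 1.99, the lowest without replicate 2 at 26 °C) and at 18 °C against 26 °C (-1.93 to 0.40, the highest without replicate 1 at 26 °C). The 44 gene values past the threshold kept their sign under each alternative except itgb1b.2 at 18 °C against 26 °C, with a range of -2.35 to 0.35 when 1 sample or array was left out. Other values that turned had not passed. Without 1 sample or array, the ranges at 34 °C against 26 °C were -1.34 to 1.36 for itgb1b.2, -0.66 to 1.78 for rpl19, -0.24 to 1.55 for cirbpa, -0.066 to 0.83 for cirbpb, -0.076 to 0.060 for hsp90aa1.1, -1.67 to 0.35 for hspa5 and -0.55 to 0.52 for hspa8. At 18 °C against 26 °C they were -0.57 to 0.20 for cirbpb, -0.046 to 0.33 for hsp90aa1.1, -0.69 to 0.97 for hspa5 and -0.16 to 0.64 for serpinh1b, and at 34 °C against 18 °C -0.37 to 0.0078 for hsp90aa1.1. With the oocyte covariate, cirbpb was -0.49 and scd -0.73 at 34 °C against 18 °C, cirbpb was -0.17 at 34 °C against 26 °C, and cirbpb was 0.32, hspa5 -0.11 and scd 0.043 at 18 °C against 26 °C. With the exocrine pancreas covariate, hsp90aa1.1 was 0.033, hspa8 -0.076 and scd 0.026 at 34 °C against 26 °C, and cirbpb was 0.059 and hspa5 -0.25 at 18 °C against 26 °C. For cirbpa at 34 °C against 26 °C, scale normalization gave -0.059, limma on the arrays -0.090, generalized least squares -0.090 and the ratio of the 25% most variable features -0.039. An alternative that also kept probes with 1 missing array was not run, since no value was missing. Without channel intensities, signal over background is unknown, and changes of weakly expressed genes cannot be told from noise near background.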

Other observations

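The curvature tests and every test of the 3 patterns at the end of this part were chosen after the results were seen, and that of exocrine pancreas tissue replaced a first version that restated its pattern; the lists and their tests were planned. Curvature is the 34 °C level plus the 18 °C level minus 2 times the 26 °C level, so it is 0 where 26 °C lies midway, and its sign turns if the deposited ratios are Cy3 over Cy5. Ribosomal protein genes had the largest median curvature of the 41 lists, at 1.00 (camera, adjusted p = 1.36e-24, and adjusted p = 0.533 with an estimated correlation). Proteasome genes had the opposite sign, at -0.60 (adjusted p = 6.77e-13, and adjusted p = 0.533 with an estimated correlation). Ribosome biogenesis genes stood at -0.49 and cholesterol genes at -0.29 (adjusted p = 3.07e-05 each, and adjusted p = 0.540 each with an estimated correlation). Genes of the insulin-like growth factor axis and stress hormones stood at 0.15 (adjusted p = 2.60e-04, and adjusted p = 0.610 with an estimated correlation).

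At 34 °C against 18 °C, further metabolic lists had positive medians. Xenobiotic and steroid metabolism had 44 of 56 genes positive, with 0 called over all features and 11 positive and 1 negative adjusted over the list alone (median 0.33, adjusted p = 3.89e-08, and adjusted p = 0.367 with an estimated correlation); its members mgst1.1 (1.24 ± 0.16) and cyp3a65 (1.23 ± 0.16) did not pass. The bile acid list had 14 of 17 positive and 1 called, the canalicular exporter abcc2 (0.60 ± 0.07), with 5 adjusted over the list alone (median 0.16, adjusted p = 0.00227, and adjusted p = 0.397 with an estimated correlation). In the respiratory chain 1 subunit was called, cox7a1 (1.77 ± 0.17), with 34 of 54 genes positive, and 8 positive and 3 negative adjusted over the list alone (median 0.24, adjusted p = 0.00564, and adjusted p = 0.512 with an estimated correlation). Gluconeogenesis and glycogen genes (median 0.39, adjusted p = 0.00287, and adjusted p = 0.427 with an estimated correlation), tricarboxylic acid cycle genes (median 0.25, adjusted p = 0.0296, and adjusted p = 0.427 with an estimated correlation) and lipogenic genes (median 0.18, adjusted p = 0.0357, and adjusted p = 0.367 with an estimated correlation) had 0 called over all features. Adjusted over the list alone, 1 gluconeogenic gene passed, 3 positive and 1 negative gene of the cycle did, and 0 lipogenic genes did. Interferon and antigen presentation genes (median 0.04, adjusted p = 6.74e-04, and adjusted p = 0.479 with an estimated correlation) and the insulin-like growth factor axis (median 0.06, adjusted p = 0.0382, and adjusted p = 0.557 with an estimated correlation) also had 0 called over all features, against 6 positive, and 2 positive and 1 negative, adjusted over the list alone. Medians of the lists that were not called were -0.06 for the proteasome, 0.01 for ribosome biogenesis, -0.05 for glycolysis, 0.03 for the circadian clock and 0.02 for hypoxia (adjusted p from 0.137 to 0.940); ribosome biogenesis was tested as negative against its positive median. Marker lists that were not called had medians of 0.28 for endocrine pancreas, 0.03 for erythrocytes, 0.02 for neutrophils and macrophages, -0.01 for lymphocytes, 0.25 for intestine, 0.03 for skeletal muscle, 0.01 for kidney, 0.02 for endothelium and stellate cells and 0.37 for biliary epithelium (adjusted p from 0.0638 to 0.897).

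Oocyte markers and liver genes had opposite signs at 34 °C against 18 °C, with medians of -2.41 and 1.21 for oocyte and hepatocyte markers, and zp2.3 ranged from -2.59 in replicate 2 at 34 °C to 2.43 in replicate 2 at 18 °C. Ovarian RNA in some samples may account for the hepatocyte part. In each of the 3 replicate pairs, replicate 1 had the lower oocyte and the higher hepatocyte median. The slope of the hepatocyte median on the oocyte median was -0.870 (-1.38 to -0.699 with each pair left out). For the ribosomal protein genes, the slope within pairs was 0.357 (0.177 to 0.677), opposite to the -0.436 between temperatures. All 3 ribosomal differences had the sign of the oocyte ones, though that at 26 °C was only -0.044. Where all pairs agree in direction, leaving out a pair cannot turn the slope, so these ranges add no check. With 3 pairs, and replicate 1 the lower in oocyte median each time, neither case can be decided. More females behind the samples with more oocyte RNA would put the vitellogenin list on the side of the oocyte markers, unless temperature moved it. Its median of 1.93 was opposite, with 10 of 11 genes positive. This cannot decide the question, because sex and temperature are not separated between these groups. Within pairs, the sample with more oocyte RNA had the higher vitellogenin median at 18 °C (-0.35 against -0.90). It had the lower one at 26 °C (-0.14 against 0.01) and at 34 °C (0.66 against 1.11). A response of the liver to temperature stays open, as untested, and so does a different amount of ovarian RNA that goes with temperature; of the 18 oocyte markers 1 is also in another list.

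Of 7 textbook temperature genes, 6 had the sign opposite to cold induction of cirbpa, cirbpb and scd and heat induction of the chaperones, with hspa8 the exception. Turned arrays, single or several, are argued against by the 28 of 28 pairs of arrays that correlated as their temperatures require, and with a dye term the residual sum was smallest of 128 patterns with no array turned (1086, against 1282 next). Without a dye term, however, 3 patterns with 2 or 3 arrays turned had smaller sums than the 3817 with none turned, the smallest 3065. Whether all deposited ratios are Cy3 over Cy5 cannot be told apart from a genuine difference after 28 days, because the exact two-sided sign test gave p = 0.125 and none of the 7 genes passed. A lasting acclimation of the liver that differs from the textbook response stays open, as untested.

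Exocrine pancreas markers differed within temperatures: amy2a was 0.49 and -1.18, and prss1 was 0.80 and -1.91, in replicates 1 and 2 at 26 °C on day 28. Temperature alone cannot make samples of 1 temperature differ, so the test of it restates the pattern. The 26 °C day 28 replicates differed by a median of 2.17, between single samples. Between the means of 34 and 18 °C, each over 2 samples, the median was 1.49. Exocrine pancreas tissue in some samples cannot be told apart from other differences between replicates: 25 of the 26 markers differed one way between the replicates that showed the pattern, but 76.9% at 34 °C and 80.8% at 18 °C. What share of any sample such tissue would make up was not tested.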
